A study of Rattus norvegicus with 24 samples.

How the data were processed

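The study measured RNA from rat heart ventricles on 2-colour microarrays, each array carrying 1 ventricle sample against a common reference pool. Per the labels, the 24 samples fall into 3 conditions written HYP, CHF and CON, all at day 14, with 8 samples each. Of these, 18 came from the right ventricle (6 per condition) and 6 from the left ventricle (2 per condition). HYP and CHF are read here as compensated hypertrophy and heart failure from the title of the series, which names monocrotaline, and CON as the control. The labels do not spell these abbreviations out and state no dose. Monocrotaline is a plant alkaloid that injures the vessels of the lung and so loads the right ventricle.

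The deposited values are a score per probe and array, and their scale is not given in the sources used here. Each array's scores had a mean between -0.0345 and 0.0713 and an SD between 0.870 and 1.01. The authors' values were therefore read as ratios against the reference pool that had been standardised within each array. Scanner, background correction, dye assignment, normalization and any filter are not given in the sources used here. A difference between groups is given in array SDs and is not a log2 fold change. The design fixed beforehand had assumed log2 ratios, and the same test was run on the scores because they are signed and centred near 0. The number of values per array ranged from 2162 to 3658 of 4803 probes, so 23.8% to 55.0% were missing. A probe was used on the arrays where it had a value. The scores carry no measure of signal over background, and the number of arrays sets the precision. The scores of 3 left ventricle arrays (CHF 15, CON 21 and CON 22) were deposited with 2 decimals and the others with 3.

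Genes were named through the platform annotation given for the probes. Of the 4803 probes, 4278 had 1 gene symbol, 4 had several and 521 had none, and 567 probes had no value on any array. Entrez identifiers looked up in the RefSeq annotation of the GRCr8 assembly, used only for names, were found for 4257 probes and changed 0 symbols. The probes gave 4126 named genes, of which 125 had more than 1 probe. A gene was the mean of its probes on each array, and probes with no symbol or with several stayed unnamed features, giving 4651 features. No coordinates are printed because no genome build was tied to the probes. The array medians lay between -0.2 and 0.217. By a rule fixed beforehand, array medians further apart than 0.2 made median centring of each array the main setting, and the deposited scores became an alternative.

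Direction was read as sample over reference pool. The lowest correlation between 2 arrays across probes was -0.530, and the dyes are not given in the sources used here, so the direction is not settled. It is called likely for the right ventricle because, of 14 anchor genes fixed beforehand, 10 were measured, 2 had an unadjusted p below 0.05 in CHF against CON by limma, and 2 of these, Acta1 and Ankrd1, went the way textbook knowledge of a pressure-loaded ventricle gives. The other measured anchors had larger p. By sign, Nppa, Nppb and Kcnd2 went that way, while Timp1, Col1a1, Col3a1, Myh6 and Kcnip2 went against it, so the direction rests on 2 genes. Ankrd1 was at 0.390 and Acta1 at 3.31 with the sign turned as below. Each comparison was repeated with the sign turned on 5 arrays. In every pair of arrays correlating below -0.3, the array with the lower median correlation with the right ventricle arrays was turned. These were CHF right ventricle arrays 10 and 14, CHF left ventricle array 09 and CON left ventricle arrays 21 and 22. This set was chosen after the correlations were seen, and an earlier form of the rule, which would have turned other arrays, was dropped.

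Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) with Benjamini-Hochberg adjustment over all features tested in a comparison, at an adjusted p below 0.05. Right ventricle comparisons used the 18 right ventricle arrays. Left ventricle comparisons, the difference between ventricles averaged over the 3 conditions, and the difference of each effect between ventricles used all 24 arrays in 6 groups. A feature needed values on at least 2 arrays of each group in its fit. The left ventricle groups hold 2 arrays each and were assumed to vary like the right ventricle groups. The labels number the samples but do not state that they are separate animals, so p-values measure only the spread between these samples, which may be technical.

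The 33 gene lists, with 1009 entries, covered cardiac pathways and cell types. They were tested with limma's camera with a preset correlation of 0.01 where at least 5 members were measured, with adjustment over all 276 tests of list and comparison. Camera with an estimated correlation and fry were alternatives, run with statmod 1.5.0 installed on features with a value on every array. Fry tests whether the genes of a list move on balance in 1 direction, and does not compare them with other genes. Data were handled with the data.table package (version 1.17.8).

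The named genes follow a rule: in right ventricle comparisons, the 10 genes with the largest positive and the 10 with the largest negative difference past the threshold, plus 2 members per list past the threshold. In the other comparisons the rule takes the 5 largest each way. Where no gene passed, the 3 with the smallest p are named with the statement that they did not pass. Measured anchor genes may be named anywhere. The samples, designs, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives chosen after seeing the data were the deposited scores without centring, the first component of the deviations from the group means as a covariate, the turned sign, the fit without CHF right ventricle arrays 10 and 14, and the fit without HYP left ventricle array 05 beyond its turn among the planned fits that leave out 1 array.

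The tests were checked on simulated data built from the residuals of these arrays, 20 times with 200 genes changed. The simulation was corrected once, because groups with a single value had given residuals of 0. For CHF against CON in the right ventricle, over a median of 3201 features, 20.1% of genes with a difference of 1, 69.9% with 2 and 94.8% with 4 were recovered, and 4.06% of calls were false. For CHF against CON in the left ventricle, over a median of 2495.5 features, the shares were 7.54%, 40.4% and 89.2%, with 8.13% of calls false, and 3 of 20 simulations with no gene changed gave calls, at most 95. For the difference between ventricles, over a median of 2495 features, they were 49.5%, 92.8% and 99.7%, with 0% false. For the CHF effect compared between ventricles, over a median of 2495.5 features, they were 6.34%, 30.3% and 79.5%, with 20.8% of calls false, above the nominal rate. In 20 simulations with no gene changed, camera called a median of 3 list tests and at most 16 of 276.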

Results

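RNA abundance in the right and left ventricles of rats was compared at day 14 between samples labelled HYP, CHF and CON. The 24 arrays comprised 6 HYP, 6 CHF and 6 CON right ventricle samples and 2 left ventricle samples of each condition. An array held between 2162 and 3658 values, and 1634 of 4803 probes had a value on every array. Differences are in array SDs with the standard error of the limma fit. Arrays of 1 group did not resemble each other much more than arrays of other groups. The median Pearson correlation across probes, where probes are not independent replicates, was 0.285 between right ventricle arrays of the same group, 0.260 between right ventricle arrays of different groups and 0.0651 between a right and a left ventricle array. The lowest was -0.530 between CHF array 14 and HYP array 08 of the right ventricle, so that the direction of the scores is not settled. The first component of the deviations from the group means held 43.3% of their variance in the right ventricle.

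**Figure D1:**
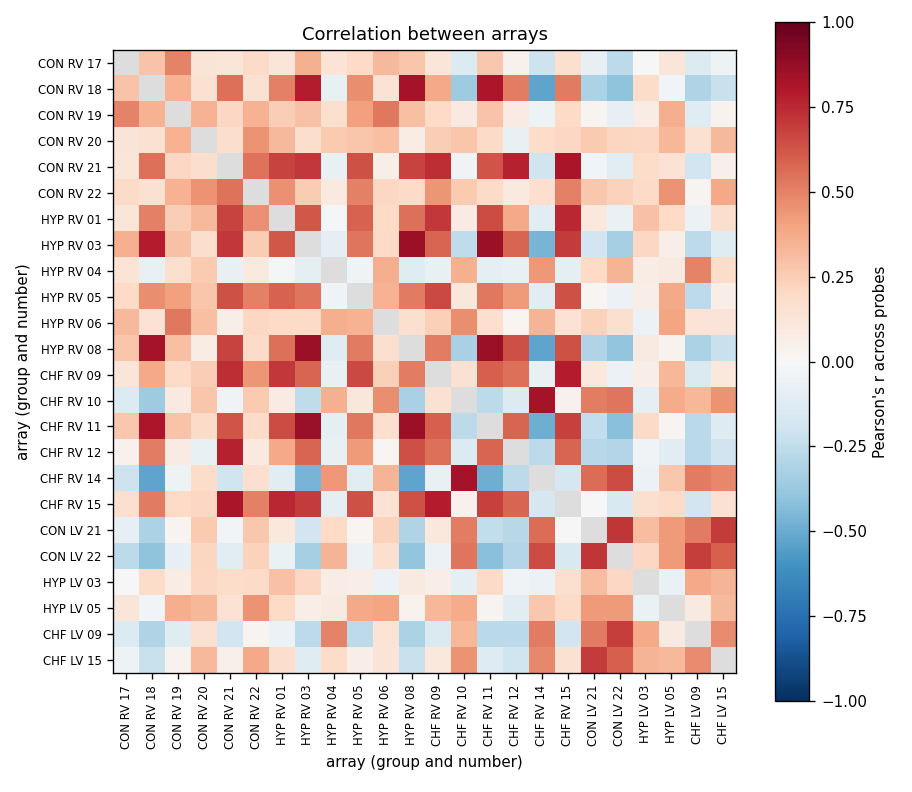
Pearson correlation across probes (colour, from -1 to 1) between all 24 arrays, ordered by ventricle, condition and array number on both axes, with the diagonal in grey. Values ran from -0.530 to 0.867, and CHF right ventricle arrays 10 and 14 correlated with each other at 0.830 but below -0.3 with 2 and 4 other arrays.

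The first comparison asked which genes differed in the right ventricle between the CHF and CON samples. Acta1, the skeletal alpha-actin of the fetal cardiac programme, was higher in CHF by 4.35 ± 0.573 array SDs (SE, n = 6 and 6, limma adjusted p = 0.000157). Acta1 and Ankrd1 are the genes by which the direction of the scores was called likely. The sign of the Acta1 difference therefore gives no separate support for that direction. Tpm3, a slow-muscle and cytoskeletal tropomyosin, was higher by 2.91 ± 0.348 (n = 6 and 6, adjusted p = 0.000122), and Tpm4, a cytoskeletal tropomyosin named here after its value was seen, by 2.90 ± 0.444 (n = 6 and 6, adjusted p = 0.000910). Cav3, the muscle caveolin, was higher by 2.69 ± 0.405 (n = 6 and 6, adjusted p = 0.000825). Cdk1, the kinase that drives entry into mitosis, was higher by 1.80 ± 0.263 (n = 6 and 6, adjusted p = 0.000593).

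Among genes of other functions, Safb, which encodes a nuclear scaffold and RNA binding protein, was higher by 4.39 ± 0.532 (n = 6 and 6, adjusted p = 0.000122). Maoa, the mitochondrial enzyme that degrades serotonin and noradrenaline, was higher by 3.66 ± 0.473 (n = 6 and 6, adjusted p = 0.000157). The calcium-binding protein gene Ocm was higher by 2.98 ± 0.377 (n = 6 and 6, adjusted p = 0.000149). The deviations of Maoa, Ocm and Safb from the group means correlated with those of Acta1 at 0.955, 0.923 and 0.846. They are therefore not shown to be findings separate from Acta1. Fgb, the fibrinogen beta chain, was higher by 1.91 ± 0.338 (n = 6 and 6, adjusted p = 0.00456), but its probes differed, at 3.34 and 0.469. The smooth muscle actin gene Acta2 was higher by 1.58 ± 0.252 (n = 6 and 6, adjusted p = 0.00132), and its 3 probes gave 4.14, 0.417 and 0.188. For Fgb, Acta2, Tpm4 and Tpm3 the correlation of the deviations with those of Acta1 was 0.844, 0.814, 0.684 and 0.622. They too are therefore not shown to be separate from it. For Cav3 and Cdk1 it was 0.414 and 0.0941. The nasal cytochrome P450 gene Cyp2g1 was higher by 3.70 ± 0.717 (n = 4 and 3, adjusted p = 0.0320).

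The 4 largest differences rested on few arrays. Clu, a secreted chaperone, was higher by 6.04 ± 0.861 (n = 2 and 3, adjusted p = 0.0197). Cfl1, which severs actin filaments, was higher by 5.92 ± 1.18 (n = 2 and 4, adjusted p = 0.0474). Cav1, the main caveolin of endothelium, was higher by 4.92 ± 0.868 (n = 2 and 3, adjusted p = 0.0302), and Kif5b, a kinesin heavy chain, by 4.75 ± 0.720 (n = 2 and 4, adjusted p = 0.0195). For all 4 genes the CHF values came from arrays 10 and 14, so that no fit could be made without either, and with the sign of those arrays turned the differences were -7.21, -3.58, -3.68 and -2.62. Leaving out CON array 20 ended the call of Clu, at 6.10, and the call of Kif5b ended without CON array 17 or 19, at 4.61 to 4.70. The call of Cav1 ended without CON array 17, 19 or 20, at 4.65 to 5.17. Cfl1 lost its call without CHF array 09 or 12 or without CON array 17, 18, 19 or 22, at 5.37 to 5.92, and Cyp2g1 without CHF array 09, 10 or 14 or without CON array 17 or 19, at 2.80 to 3.84.

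Of 3199 features tested, 29 passed, 28 higher and 1 lower, and 272 had an unadjusted p below 0.05. Of the 28 that were higher, 25 were named genes, and the lower one was an unnamed probe. The groups did not overlap for 26 of the 29. Over all features with values on the 12 arrays, 1.45% did not overlap, against 0.216% by chance. With the sign turned on CHF arrays 10 and 14 the count was 9, of which 8 were among the 29. Safb, Tpm3 and Cdk1 still passed, at 3.84, 2.35 and 1.77, while Acta1, Maoa, Ocm, Cav3, Fgb, Acta2 and Cyp2g1 did not, at 3.31, 2.70, 2.26, 1.99, 1.30, 1.25 and 1.22. The count was 17 without CHF array 10, 16 without CON array 19 and 18 without CHF arrays 10 and 14.

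**Figure D2:**
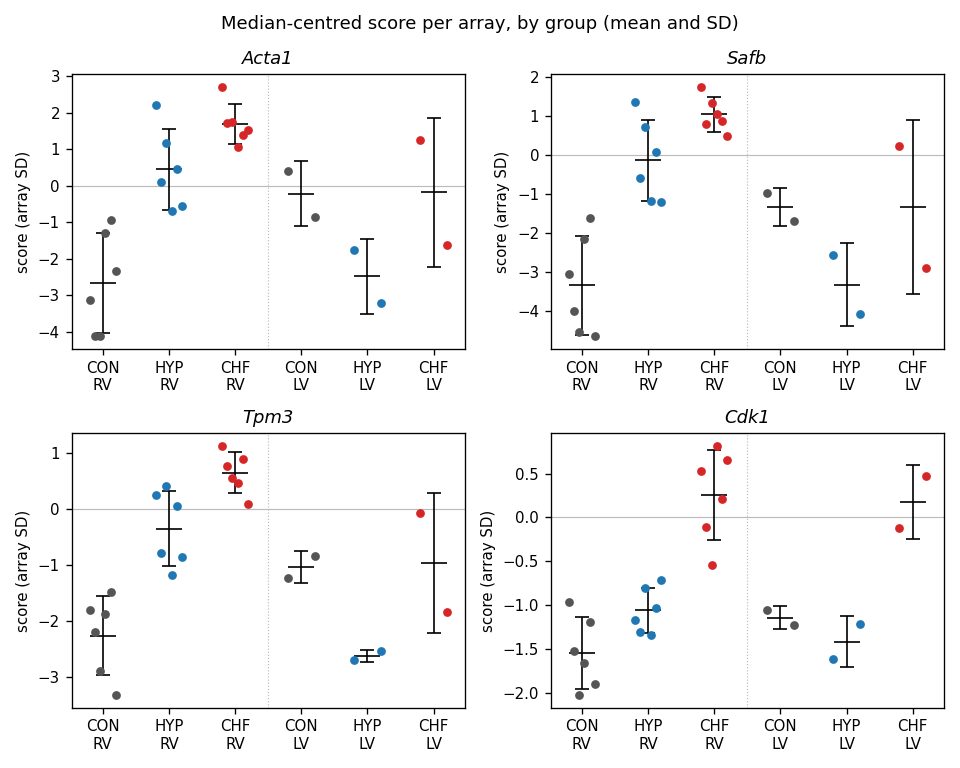
Median-centred score (array SDs) of Acta1, Safb, Tpm3 and Cdk1 on each array, by condition and ventricle. Points are arrays and bars are the mean and SD, with 6 right and 2 left ventricle arrays per condition. In the right ventricle every CHF array lay above every CON array for these 4 genes.

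Gene lists fixed beforehand gave a partial picture of the same comparison. In the fetal and hypertrophy list 2 of 13 measured members rose, Acta1 and Acta2, and 3 adjusted over the list alone. The list stood higher than other genes (median difference 0.599, limma camera adjusted p = 0.0289, and adjusted p = 0.354 with an estimated correlation). The cell cycle list had 1 of 16 members higher, Cdk1, and 3 adjusted over the list alone (median 0.293, adjusted p = 0.0128, and adjusted p = 0.358 with an estimated correlation). Among 9 smooth muscle and pericyte markers, Acta2 rose and 2 adjusted over the list alone (median 0.343, adjusted p = 0.00941, and adjusted p = 0.291 with an estimated correlation, fry adjusted p = 0.0150). Acta2, counted here and in the fetal list, rose mainly on 1 of its 3 probes, at 4.14 against 0.417 and 0.188. Cytosolic ribosomal protein genes stood lower, with 0 of 61 past the limma test alone, 8 of 61 differences above 0 and a median of -0.312 (adjusted p = 0.00496, and adjusted p = 0.960 with an estimated correlation).

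Other classical markers of the loaded ventricle did not pass. Ankrd1, a stress-responsive ankyrin repeat protein, differed by 1.56 ± 0.418 (n = 6 and 6, limma adjusted p = 0.112). Of the alternatives it passed without CHF array 12, at 1.83, and with the array component as a covariate, and it fell to 0.390 with the sign turned (adjusted p = 0.766). Nppa and Nppb, the natriuretic peptide genes, differed by 1.85 ± 1.94 (n = 3 and 5, adjusted p = 0.822) and 0.621 ± 0.442 (n = 3 and 4, adjusted p = 0.734). Nppa reversed with the sign turned, at -1.03, and with arrayWeights, at -0.0740. It was 1.03 without CHF array 10, 4.41 without CHF array 11, 0.109 without CHF array 14, 1.02 without CON array 18 and 2.89 without CON array 22, and Nppb was 0.362 without CON array 19, 0.981 without CON array 20 and 1.34 with the sign turned. Col1a1 differed by -0.107 ± 0.282 (n = 6 and 6, adjusted p = 0.932), and 17 collagen and matrix genes had a median of -0.107 with 0 past the test (camera adjusted p = 0.869). Fatty acid uptake and oxidation genes had a median of -0.435 over 29 members (camera adjusted p = 0.0678), and the tricarboxylic acid cycle and respiratory chain genes -0.379 over 34 (adjusted p = 0.152). Macrophage and monocyte markers (7 measured, median -0.0333, adjusted p = 0.973), endothelial markers (7 measured, median 0.134, adjusted p = 0.737) and fibroblast markers (9 measured, median -0.228, adjusted p = 0.831) did not pass either. The 4 measured erythrocyte markers, too few for camera, had a median of 0.990, and of 0.923 in CHF against HYP.

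The second comparison asked which genes differed between the HYP and CON right ventricles. The 8 named genes that passed were all higher in HYP and had also risen in CHF. Safb was higher by 3.21 ± 0.532, Acta1 by 3.11 ± 0.573, Maoa by 2.47 ± 0.473 and Ocm by 2.05 ± 0.377 (SE, n = 6 and 6 for each, limma adjusted p = 0.0121, 0.0174, 0.0226 and 0.0174). Cav3 was higher by 1.98 ± 0.405, Tpm3 by 1.91 ± 0.348, Capn3, a muscle calpain, by 1.74 ± 0.294, and Bdkrb1, the bradykinin B1 receptor gene, by 1.54 ± 0.318 (n = 6 and 6, adjusted p = 0.0418, 0.0174, 0.0121 and 0.0422). The fetal and hypertrophy list had 1 of 13 members higher, Acta1, and 2 adjusted over the list alone (median 0.158, camera adjusted p = 0.0329, and adjusted p = 0.354 with an estimated correlation). Ankrd1 differed by 0.878 ± 0.418 (n = 6 and 6, limma adjusted p = 0.9997). Over the right ventricle arrays, deviations from the group means correlated with those of Acta1 at 0.955 for Maoa, 0.923 for Ocm and 0.846 for Safb. The values were 0.773 for Capn3, 0.702 for Bdkrb1, 0.622 for Tpm3 and 0.414 for Cav3. Apart from Cav3, these genes are therefore not shown to be findings separate from Acta1.

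Of 3199 features 9 passed, all higher, with 131 at an unadjusted p below 0.05, and the groups did not overlap for 9 of 9. Over all features with values on the 12 arrays, 0.759% did not overlap, against 0.216% by chance. The calls depended on single arrays and on the estimate of the spread. The count was 3 without HYP array 01, 04 or 06 or without CON array 18, 19 or 22, and 4 without CON array 17. Fitting the 2 groups alone gave 0, with 139 at an unadjusted p below 0.05. With the sign turned on the doubtful CHF arrays, which enter the estimate of the spread, 1 passed, an unnamed probe, and none of the 8 named genes did (adjusted p = 0.0676 for Safb and 0.136 for Capn3). Safb and Capn3 kept their calls in all 12 fits that left out 1 array, while Acta1, Maoa, Ocm, Cav3, Tpm3 and Bdkrb1 lost theirs without the arrays just named (Tpm3 kept its call without CON array 17). The differences there were 2.75 to 3.17 for Acta1, 2.12 to 2.46 for Maoa, 1.81 to 2.02 for Ocm, 1.71 to 2.11 for Cav3, 1.69 to 1.92 for Tpm3 and 1.35 to 1.60 for Bdkrb1. Cav3 also lost its call without CON array 21 and Bdkrb1 without CON array 20.

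The 9 features called in HYP were all called in CHF in the same direction. Most of them varied together with Acta1 within groups, so they are not shown to be 9 separate findings. Independent lists would share 0.0788, and a simulation of unchanged groups against the same 6 controls gave a median of 0 and at most 1. Unchanged groups give hardly any calls, so this simulated count cannot show what common controls alone add once a group differs. With the controls split 3 and 3 between the comparisons, a median of 1 was shared (range 0 to 9 over 20 splits). The differences correlated across features at 0.579 against a simulated median of 0.501 and at most 0.843, and at a median of 0.0795 with split controls. Their covariance was 0.205 against a simulated median of 0.143 and at most 0.498, a difference of 0.0627 from the median. Both observed values lay below the highest simulated ones, so no excess over common controls is shown by them. Of 28 features higher in CHF, the HYP mean lay between the CON and CHF means for 28. The median difference from CON was 2.37 in CHF and 1.20 in HYP, over features selected for the CHF difference. Turning the sign of CHF arrays 10 and 14 left the HYP mean between for 18 of the 28, with medians of 1.26 and 1.20.

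The third comparison set the CHF against the HYP right ventricles. No feature passed in limma, with 158 of 3199 at an unadjusted p below 0.05. The genes with the smallest p were Cdk1, which differed by 1.32 ± 0.263 (n = 6 and 6, adjusted p = 0.258), Dpysl2, a regulator of microtubule assembly, by 3.29 ± 0.622 (n = 2 and 2, adjusted p = 0.697), and Itpka, an inositol trisphosphate kinase gene, by 1.26 ± 0.319 (n = 6 and 6, adjusted p = 0.697). These did not pass. Acta1 differed by 1.24 ± 0.573 (n = 6 and 6, adjusted p = 0.938). The proteasome and ubiquitin list stood lower in CHF, with 0 of 27 members past the test and a median of -0.190 (camera adjusted p = 0.0285, and adjusted p = 0.960 with an estimated correlation). The limma count was 1 without CHF array 11, where Cdk1 passed at 1.48, and 1 with arrayWeights, again Cdk1. With the sign turned it was 1, lower in CHF, the difference of Dpysl2 became -1.42, and the proteasome list had a median of -0.041 with its camera direction reversed.

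In the left ventricle, where each condition had 2 samples, limma called 0 of 2494 features in each of the 3 comparisons. For CHF against CON, with 22 at an unadjusted p below 0.05, Pdc differed by -1.70 ± 0.470, Zp1 by 1.91 ± 0.603 and Lcat by 1.68 ± 0.532 (n = 2 and 2, adjusted p = 0.9998 for each). Acta1 differed by 0.0365 ± 1.06 (n = 2 and 2, adjusted p = 0.9998), by -2.26 ± 1.06 in HYP against CON (adjusted p = 0.996) and by 2.30 ± 1.06 in CHF against HYP (adjusted p = 0.958). For HYP against CON, with 46, Clu differed by -2.99 ± 0.865, Cr1l by 2.15 ± 0.726 and Fgfr1 by -1.81 ± 0.610 (n = 2 and 2, adjusted p = 0.996 for each). For CHF against HYP, with 75, Ccnb1, the cyclin partner of Cdk1, differed by 2.56 ± 0.564, Lrit1 by 1.73 ± 0.435 and Cdk1 by 1.59 ± 0.427 (n = 2 and 2, adjusted p = 0.565 for each).

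Several lists moved in the left ventricle by the camera test, and none with an estimated correlation. Cytosolic ribosomal protein genes stood higher in CHF than in CON (median 0.296, 0 of 60 past the gene test, adjusted p = 0.000139, and adjusted p = 0.842 with an estimated correlation). They also stood higher in HYP (median 0.351, 0 of 60, adjusted p = 0.0128, and adjusted p = 0.960 with an estimated correlation). Cell cycle genes stood higher in CHF than in CON (median 0.427, 0 of 14 past the gene test and 2 adjusted over the list alone, adjusted p = 0.000139, and adjusted p = 0.230 with an estimated correlation) and than in HYP (median 0.758, 0 of 14 and 4 adjusted over the list alone, adjusted p = 0.000372, and adjusted p = 0.327 with an estimated correlation). Smooth muscle and pericyte markers stood lower in HYP than in CON (median -0.737, 0 of 8, adjusted p = 0.00312, and adjusted p = 0.358 with an estimated correlation) and higher in CHF than in HYP (median 0.708, 0 of 8, adjusted p = 0.0114, and adjusted p = 0.527 with an estimated correlation). The proteasome and ubiquitin list stood higher in HYP than in CON (median 0.239, 0 of 27, adjusted p = 0.0458, and adjusted p = 0.960 with an estimated correlation).

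The 4 measured erythrocyte markers, too few for camera, had a median of -4.49 in HYP against CON, 2.95 in CHF against HYP and -1.43 in CHF against CON of the left ventricle. HYP left ventricle array 05, where haemoglobin genes were low, is 1 of the 2 HYP arrays in the first 2 of these differences.

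The left ventricle results depended on single arrays and on the sign. The 3 turned left ventricle arrays correlated above 0 with the other 3 (0.0904 to 0.696), which argues against a reversed sign on them alone. Without HYP array 03, 4 features passed in HYP against CON and 5 in CHF against HYP. With the sign turned, HYP against CON gave 96 (48 higher and 48 lower), where Clu differed by 4.95, CHF against HYP gave 0 with 88 at an unadjusted p below 0.05, and CHF against CON gave 0 with 178. The cell cycle list in CHF against CON then stood lower, with a median of -0.8355, and in HYP against CON the proteasome median became -0.107. Pdc and Zp1 reversed to 0.311 and -0.3745, and Cr1l and Fgfr1 to -1.37 and 0.7765. Leaving out CHF array 15 moved Zp1 to 1.25, and leaving out HYP array 05 moved Cr1l to 1.24. On the deposited scores the median of all features in HYP against CON lay at 0.147 instead of 0.0393, and 0 passed.

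The right and left ventricle arrays differed in 457 of 2494 features averaged over the conditions, 294 higher and 163 lower in the right ventricle, with 901 at an unadjusted p below 0.05. The tissue cannot be told apart here from any separate processing of the left ventricle arrays. Only left ventricle arrays (CHF 15, CON 21 and CON 22) were deposited with 2 decimals. Myl9, a smooth muscle myosin light chain, was higher in the right ventricle by 2.18 ± 0.311 (SE, n = 18 and 6, limma adjusted p = 0.000157). The growth factor gene Igf1 was higher by 2.09 ± 0.387 (n = 17 and 6, adjusted p = 0.00250), Apoe, the lipid carrier, by 1.95 ± 0.278 (n = 18 and 6, adjusted p = 0.000157), Hcn2, a pacemaker channel gene, by 1.86 ± 0.165 (n = 18 and 6, adjusted p = 3.55e-07), and complement gene C4b by 1.75 ± 0.376 (n = 18 and 6, adjusted p = 0.00560).

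Haemoglobin genes were lower in the right ventricle. The difference was -6.29 ± 1.18 for Hba-a1 and -5.89 ± 1.22 for Hbb (n = 18 and 6, limma adjusted p = 0.00250 and 0.00462). Without HYP left ventricle array 03 they were -4.00 and -3.76 (adjusted p = 0.00457 and 0.0231). Hbb-b1 fell too (adjusted p = 0.00116), and with Alas2, the enzyme that starts haem synthesis in red cells, 4 of 4 measured erythrocyte markers passed, with a median of -5.44. Alas2 did not follow the haemoglobin genes from array to array. It was at -0.604 on HYP left ventricle array 03, where Hbb was at 5.36, and at 0.956 on array 05, where Hbb was at -7.40. Tap2, a peptide transporter gene of antigen presentation, differed by -5.45 ± 0.937 (n = 16 and 6, adjusted p = 0.00155) and Penk, which encodes proenkephalin, by -3.36 ± 0.690 (n = 18 and 6, adjusted p = 0.00425). Tap2 tracked Hbb, at 4.84 beside 5.36 on HYP left ventricle array 03 and -5.89 beside -7.40 on array 05. Its difference is therefore not shown to be separate from that of the haemoglobin genes. On the HYP left ventricle array 05, Hbb was at -7.40, among the right ventricle values, and Hba-a1 at -8.04, below all of them, while the other left ventricle arrays had Hbb between 2.05 and 5.59.

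The tricarboxylic acid cycle and respiratory chain list stood lower in the right ventricle, with 7 of 34 members lower, among them Cox6a2 and Atp5mc1 (7 adjusted over the list alone, median -0.410, camera adjusted p = 0.00205, and adjusted p = 0.825 with an estimated correlation). Of 8 adult sarcomere genes, Ckm, Ttn and Myl3 fell and 4 adjusted over the list alone (median -1.02, adjusted p = 0.0573). Of 8 smooth muscle and pericyte markers, Myl9 and Acta2 rose (median 0.247, camera adjusted p = 0.833, fry adjusted p = 0.0150). Of 12 fetal and hypertrophy genes, Tnni1, Ccn2 and Acta2 rose (median 0.556, camera adjusted p = 0.277, fry adjusted p = 0.0136). Collagen and matrix genes went both ways, with 5 of 13 higher and 2 lower. Timp1, an inhibitor of matrix proteases, differed by -1.07 ± 0.350 (n = 18 and 6, limma adjusted p = 0.0408).

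With the sign turned on the 5 doubtful arrays, limma called 0 features between the ventricles, with 299 at an unadjusted p below 0.05, and no gene named here passed. Acta2 reversed to -0.0399, and the other named genes kept their direction, among them Hcn2 at 0.276 and Hbb at -1.51. The respiratory chain list then stood higher, with a median of 0.448. The count was 264 without HYP left ventricle array 03, 140 without CHF array 09, 269 without CHF array 15, 160 without CON array 21 and 153 without CON array 22. On the deposited scores it was 563 (425 higher and 138 lower), where the median of all features lay at 0.197 instead of 0.0344.

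**Figure D3:**
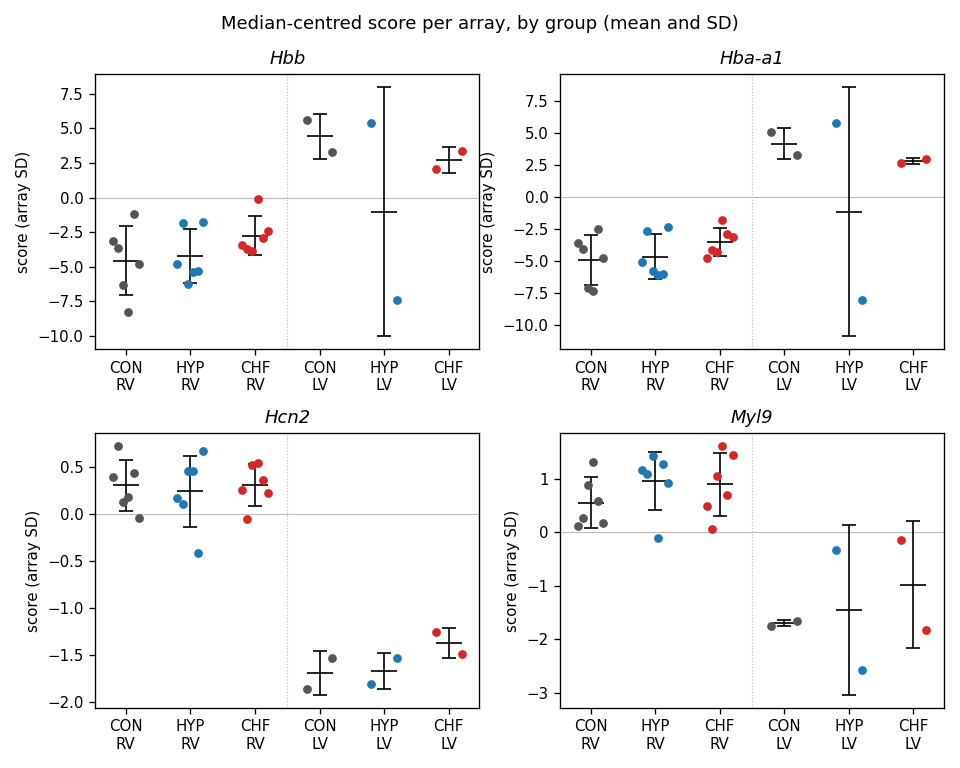
Median-centred score (array SDs) of Hbb, Hba-a1, Hcn2 and Myl9 on each array, by condition and ventricle. Points are arrays and bars are the mean and SD, with 6 right and 2 left ventricle arrays per condition. The HYP left ventricle array 05 had Hbb at -7.40, among the right ventricle arrays, and Hcn2 at -1.53, among the left ventricle arrays.

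The last comparisons tested whether the effects of CHF and HYP differed between the ventricles. No feature passed in limma for CHF (68 of 2494 at an unadjusted p below 0.05) or for HYP (62). Among named genes the smallest p for CHF belonged to Clu, with an effect larger in the right ventricle by 7.22 ± 1.17, Maoa by 4.59 ± 0.975 and Bdkrb1 by 2.93 ± 0.655 (adjusted p = 0.0909, 0.0909 and 0.124). Clu had values on 2 CHF and 3 CON arrays of the right ventricle, and the others on all arrays. For HYP it belonged to Tpm3 at 3.48 ± 0.712, Maoa at 4.73 ± 0.975 and Capn3 at 2.95 ± 0.645 (adjusted p = 0.0644, 0.0644 and 0.0773), and Acta1 differed by 5.37 ± 1.22 (adjusted p = 0.0824). A lower left ventricle mean in HYP than in CON is a part of each of these HYP differences. The means were -2.61 and -1.03 for Tpm3, -1.61 and 0.645 for Maoa, -1.81 and -0.595 for Capn3, and -2.48 and -0.22 for Acta1 (n = 2 and 2). None of the CHF and HYP differences named here passed. So the right ventricle increases were not shown to differ from the left ventricle by this test.

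By camera, the effect on cytosolic ribosomal protein genes was lower in the right ventricle for CHF (median -0.611, 0 of 60 members past the gene test, adjusted p = 6.14e-06, and adjusted p = 0.795 with an estimated correlation) and for HYP (median -0.482, 0 of 60, adjusted p = 0.000842, and adjusted p = 0.960 with an estimated correlation). The effect on smooth muscle and pericyte markers was higher for CHF (median 0.452, 0 of 8, 1 adjusted over the list alone, adjusted p = 0.0279) and for HYP (median 1.02, 0 of 8, 1 adjusted over the list alone, adjusted p = 0.000329), and for both adjusted p = 0.291 with an estimated correlation. The limma count for CHF was 1 without CON right ventricle array 19, 6 without CHF left ventricle array 09 and 9 with the sign turned, where Clu differed by -11.1 and the smooth muscle list had a median of -0.649. Clu passed at 7.92 without CON right ventricle array 19, and Maoa and Bdkrb1 at 5.73 and 3.74 without CHF left ventricle array 09. For HYP it was 4 without HYP right ventricle array 05, 8 without CON right ventricle array 21, 4 without HYP left ventricle array 03 and 33 with the sign turned. Tpm3, Maoa and Capn3 passed without HYP right ventricle array 05, at 3.65, 4.95 and 3.15, and without CON right ventricle array 21, at 3.64, 4.98 and 3.04.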

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

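The test of the probes that follow Acta1, whose verdict was also made stricter once its bound was seen, the addition of called muscle genes to the skeletal muscle markers, the share of the ventricle difference along the array component, the correlations of the turned left ventricle arrays, and the count of genes on either side of the ventricles for HYP left ventricle array 05, were chosen only after the result was seen. Of the other tests, the label splits were planned, and those of the skeletal muscle markers alone and of the position of array 05 were set before their results.

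A sample far from the others of its group appeared in 5 of 106 groups tested over 38 quantities, where chance alone gives about 1 in 20. The gap to the nearest sample over the range was 0.891 for Cyp2g1 in CHF right ventricle array 11, 0.737 for Lcat in CHF array 14, 0.812 for Lrit1 in HYP array 06, 0.665 for Myl9 in HYP array 05, and 0.835 for the SD of CHF array 12. CHF array 12 also held the fewest values, 2162.

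Gene lists whose effect differed between the ventricles by camera were the cytosolic ribosomal proteins for CHF (adjusted p = 6.14e-06) and HYP (adjusted p = 0.000842) and the smooth muscle and pericyte markers for CHF (adjusted p = 0.0279) and HYP (adjusted p = 0.000329). None passed with an estimated correlation, where the adjusted p was 0.795, 0.960, 0.291 and 0.291.

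Other splits of the right ventricle arrays were tried for each comparison there. For CHF against CON, 1 of 100 splits gave as many calls, the real one, with 29 against at most 17 in the others. For HYP against CON it was also 1 of 100, with 9 against at most 0 by limma, where the real comparison had 131 features at an unadjusted p below 0.05. For CHF against HYP the real split gave 0 calls by limma (158 at an unadjusted p below 0.05), which all 100 splits must reach, so the splits say nothing about chance there.

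Part of the features that rose in the CHF right ventricle varied together with Acta1: over 27 of them the correlation of deviations from the group means with Acta1 ran from -0.337 to 0.955 with a median of 0.622, against -0.0263 over 3170 features that did not pass. It was above 0.534, the 95th percentile of the latter, for 14 of the 27, among them Maoa (0.955), Ocm (0.923) and Safb (0.846). For Cdk1, Itpka, Dynlt1, Cav1, Top1 and Clu it was below 0.1. Skeletal muscle in the samples would raise its abundant transcripts together. The rise had a median of 2.37, while 14 measured markers had a median of -0.316 (SE 0.186, from -1.23 to 0.777). Of these markers 0 passed in limma, with 272 of all features at an unadjusted p below 0.05. With the muscle genes Tpm3, Cav3, Capn3 and Pvalb added because they rose, the median was -0.158 (SE 0.366). The markers include genes such as Myog and Chrnd that need not be abundant. Among fast-muscle contractile genes, picked out after the result was seen, Tnni2 and Tnnt3 stood at 0.777 and 0.672. Myl11, Myh1 and Tnnc2 stood at -0.0266, -0.470 and -0.753. These values argue against skeletal muscle as the source of the rise as a whole, but a small share is not excluded. Whether several probes might read the Acta1 transcript cannot be told apart from shared regulation, because probes of 1 gene correlated at a median of only 0.0727 and gave no usable bound. The 0.918 of 1 Acta2 probe against 0.255 and -0.129 of the others, and the 0.959 of 1 Fgb probe against 0.325, keep that explanation open beside a shared response to load, which was not tested.

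The count of 457 features between ventricles did not come from chance splits of the arrays alone, since 1 of 100 splits within conditions gave as many, the real one, and the highest other gave 215. That other split put HYP 04, CHF 14 and CON 22 of the right ventricle with HYP 05, CHF 09 and CON 22 of the left. Its 3 left ventricle arrays may give part of its calls, though splits with 4 left ventricle arrays gave at most 4. Whether a structure of the arrays beyond the groups adds to it was not tested. Whether the array component within groups made this difference cannot be told apart from the ventricles, because over 347 called features 0.408 of the squared difference lay along its loading, and 0.336 to 0.556 with 1 array left out. The 961 calls with the component as a covariate decide nothing, since its mean is 0 in each group. The loss of all limma calls with the sign turned on 5 arrays (299 at an unadjusted p below 0.05) decides nothing either, since these arrays were picked by their correlations and include 3 of the 6 left ventricle arrays, which correlated with the other 3 at 0.0904 to 0.696. Those 9 correlations, all above 0, argue against a reversed sign on these 3 left ventricle arrays alone. CHF right ventricle arrays 10 and 14 had Hbb at -3.745 and -2.935 unturned, among the other right ventricle arrays (-8.295 to -0.133). Their correlations with other arrays, down to -0.530, go the other way, so their sign stays open. The left ventricle as a tissue was not tested apart from any separate processing of its arrays.

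HYP left ventricle array 05 stood apart from the other left ventricle arrays. On a scale from 0 (left) to 1 (right) over 200 genes that separate the ventricles in other arrays, it lay at 0.678, inside the right ventricle range of 0.330 to 1.33 and above the other left ventricle arrays (-0.0815 to 0.227). This is consistent with right ventricle tissue under a left ventricle label. Of 49 genes that separate the other arrays without overlap, it lay on the left ventricle side for 12 (24.5%), against 0% to 45.6% for right and 66.2% to 89.1% for the other left ventricle arrays. Hcn2 at -1.53, Myl9 at -2.58, Apoe at -1.86 and C4b at -2.51 lay below every right ventricle array, on the left ventricle side. Igf1 at -0.246 and Penk at -0.912 lay among the right ventricle arrays, and the haemoglobin genes and Tap2 were as low as there or lower. The label therefore stays open, and no biological explanation was tested.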

How the results depend on the processing

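The alternatives chosen after seeing the data are the turned sign, the array component as a covariate, the deposited scores and the fits without CHF right ventricle arrays 10 and 14 or without HYP left ventricle array 05. For all changes given here the cause was not tested.

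With the sign turned on 5 arrays, the count of features past the limma test went from 29 to 9 for CHF against CON in the right ventricle (8 shared), from 9 to 1 for HYP against CON, from 0 to 1 for CHF against HYP, from 0 to 96 for HYP against CON in the left ventricle, from 457 to 0 between ventricles (299 at an unadjusted p below 0.05), from 0 to 9 for the CHF effect and from 0 to 33 for the HYP effect between ventricles. Calls shared by HYP and CHF went from 9 to 1, and list calls from 18 to 34. Of the 28 features called higher in CHF against CON of the right ventricle, 23 stayed above CON. Among genes named by the rule, the direction reversed in CHF against CON of the right ventricle for Clu (-7.21), Cfl1 (-3.58), Cav1 (-3.68), Kif5b (-2.62) and Nppa (-1.03), in CHF against HYP for Dpysl2 (-1.42), and in the left ventricle for Pdc (0.311), Zp1 (-0.3745), Clu (4.95), Cr1l (-1.37) and Fgfr1 (0.7765). It also reversed for Clu in the CHF effect between ventricles (-11.1). The camera direction reversed for the lists of the proteasome in CHF against HYP of the right ventricle (median -0.041, which kept its sign), the cell cycle in CHF against CON of the left ventricle (-0.8355), the respiratory chain between ventricles (0.448) and smooth muscle in the CHF effect (-0.649). The proteasome median in HYP against CON of the left ventricle became -0.107, while its camera direction stayed.

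Other settings moved fewer counts. With the array component as a covariate, the counts were 49 for CHF against CON (26 shared), 961 between ventricles (457 shared) and 4 for the HYP effect. With arrayWeights they were 1 for CHF against HYP, 1066 between ventricles and 3 for the CHF effect, and Nppa reversed to -0.0740 in CHF against CON. Without CHF arrays 10 and 14 they were 18 (17 shared) and 863. Only the compared groups gave 0 for HYP against CON (139 at an unadjusted p below 0.05). Only features with a value on every array gave 1 for the CHF and 7 for the HYP effect, and each probe on its own gave 4 for the HYP effect. Controls split 3 and 3 gave a median of 1 shared call. Camera with an estimated correlation called 0 lists and fry 3. Quantile normalization, robust eBayes and the deposited scores left every count within 1.5 times, or at 0.

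Leaving out 1 array at a time gave 16 to 38 calls for CHF against CON, 3 to 9 for HYP against CON and 0 to 1 for CHF against HYP in the right ventricle. In the left ventricle it gave 0 to 0 for CHF against CON, 0 to 4 for HYP against CON and 0 to 5 for CHF against HYP. It gave 140 to 683 between ventricles, 0 to 6 for the CHF effect, 0 to 8 for the HYP effect and 3 to 9 shared calls. Over all alternatives, 731 of 847 values of called genes kept direction and call, 112 lost the call and 4 reversed, and of 198 list values 135 were kept, 59 lost the call and 4 reversed. Of 416 values of genes not called, 377 stayed so, 30 passed and 9 reversed.

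Right and left ventricle samples share numbers, and whether a number marks 1 animal is not stated. Deviations of same-numbered samples correlated at -0.232 to 0.317, above 0.1 in 3 of 6, and 2 of 6 correlated best with their own number, so they were not treated as pairs. The check is weak, since the 2 left ventricle deviations of a condition mirror each other. With the number as a random replicate block (correlation 0.231) 739 features passed between ventricles, 4 in the CHF and 6 in the HYP effect. With it as a fixed block on 12 arrays, 889, 0 and 0 passed.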

Other observations

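The left ventricle values of the features that rose in CHF, described here, were examined only after the result was seen, as were the genes named here, which lie outside the naming rule.

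Further genes rose in the CHF right ventricle with the signs as deposited. With the sign turned on the doubtful CHF arrays there, 23 of the 28 features that rose stayed above CON. Of the 9 features that then passed limma, 8 had also passed unturned. Which of the genes below were among them is not shown here, so their direction is not settled. Tuba1b, an alpha-tubulin, was higher than in CON by 1.41 ± 0.331 and Dynlt1, a dynein light chain, by 1.37 ± 0.259 (SE, n = 6 and 6, limma adjusted p = 0.0478 and 0.00957). Pvalb, a calcium buffer of fast muscle and a relative of Ocm, was higher by 1.18 ± 0.243 (n = 6 and 6, adjusted p = 0.0195), and Anxa1, a calcium-dependent phospholipid binding protein, by 1.03 ± 0.218 (n = 6 and 6, adjusted p = 0.0210). Top1, which relaxes DNA supercoils, was higher by 2.83 ± 0.445 (n = 3 and 3, adjusted p = 0.0210) and Clock, of the circadian clock, by 1.30 ± 0.299 (n = 6 and 6, adjusted p = 0.0420).

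Of the 28 features that rose in the CHF right ventricle, 25 were measured in the left ventricle, where 14 were higher in CHF than in CON, with a median difference of 0.0365 array SDs. The median does not hold for each feature. Itpka and Cdk1 differed by 1.51 ± 0.682 and 1.31 ± 0.427, and Clu and Maoa by -1.18 ± 0.865 and -0.929 ± 0.844 (SE, n = 2 and 2). None of them passed in limma. When CHF array 09 and CON arrays 21 and 22 of the left ventricle had their sign turned, 4 were higher, with a median of -0.866, so no direction there is shown.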
